A study of Homo sapiens with 2 samples.

How the data were processed

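The series held 2 libraries made by CUT&Tag, an assay in which an antibody tethers a Tn5 transposase to chromatin so that the DNA next to the antibody's target is cut and tagged for sequencing. Both came from untreated NB4 cells, a human acute promyelocytic leukaemia cell line that carries the PML::RARA fusion. In 1 library the antibody was against LDB1 and in the other it was a non-specific IgG. Per the labels' protocols, both were made with the Hyperactive Universal kit from Vazyme.

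The values used were the deposited positions and widths of the LDB1 peaks. Per the file headers these were the chromosome, the start, the end and the length of each peak in bp. Starts and ends counted from 1 and were inclusive, since the length equalled the end minus the start plus 1 in all 53742 rows. The submitters' processing notes named the hg38 build, Bowtie2 2.4.1 (an aligner) and MACS2 2.0.10 (a peak caller). The parameters, the threshold, the handling of duplicate reads and of reads that align to several places, any excluded regions, and whether the IgG library served as the caller's control are not given in the sources used here. The peaks came from 1 library and were therefore not pooled. The table used held no height, fold, score, p, q, summit or read total, so the depth was unknown, and no background level in the IgG library was analysed here.

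How a list of this kind is made affects what can be measured from it. Peak number and width both rise with depth and with a looser threshold. Neighbouring peaks were at least 324 bp apart, and a broad enriched region could be listed as several neighbouring peaks. The Tn5 transposase prefers open chromatin, and such background can be counted as peaks where it is not subtracted. A binding strength was not measured, and width stood in its place.

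Genes were taken from a RefSeq gene table of the GRCh38.p14 assembly, the build the peaks use, with each gene's symbol, biotype, chromosome, start and end. It held 19974 protein-coding genes on chromosomes 1 to 22 and X and 59098 genes of all kinds there. It gave no strand, exons or sequence. Several parts of the plan fixed before the data were examined were therefore changed. The promoter became the 1 kb to either side of either end of a protein-coding gene, so that the transcription start and the transcription end were not told apart. Exons and introns were joined as the rest of the gene body. The peak midpoint replaced the summit, and width replaced fold wherever peaks were ranked. Random gene lists for gene ends were matched on gene length in place of promoter GC content. Stretches of 1 Mb or more with neither a gene nor a peak were left out of random placement in place of assembly gaps. The planned search for 26 sequence motifs, the share of motifs by peak strength and the filter on repeats were not run.

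The main set was the 52765 peaks on chromosomes 1 to 22 and X. Each peak midpoint was assigned first to a gene end (within 1 kb), then to the rest of a gene body, and otherwise to the sequence outside genes. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error within this peak list only. Shares were set beside 1000 random placements of the same peak widths on the same chromosomes, and ratios are the observed count over the mean of the placements. Peaks 10 kb or less apart were joined into clusters, and clusters of at least 5 peaks were counted in the same placements. Peaks per Mb of each chromosome were set beside the range expected if all peaks fell evenly over the placeable sequence.

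The 18 gene lists, with 360 distinct genes, were fixed before the data were examined, and all 360 were found in the gene table. For each list the share of genes with a peak at a gene end, the share with a peak in the gene body or within 10 kb of it, and the median number of such peaks were set beside 10000 random lists of protein-coding genes of the same size, matched in 10 equal classes of gene length. A list was called above or below the random lists when at most 50 of the 10000 reached its value from that side. With 1 library per antibody no test between samples was possible and no p-value is given; the counts of placements and random lists describe this peak list only.

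The genes named were chosen by a rule fixed before the data were examined, with width in place of fold. It allowed every member of the LDB1 complex, stem and progenitor, myeloid factor and granulocyte lists, the 4 members with the widest peak and up to 3 members without a peak of each other list, the 10 widest peaks with a midpoint at gene ends and the 10 widest with a midpoint elsewhere, and the 5 clusters with the most peaks with their genes. Genes named outside the rule were chosen after their values were seen and are said to be so where they appear, and a few genes that the rule allowed are not reported here.

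The alternatives tried changed 1 choice at a time. They were the widest 50% or 25% of the peaks, other distances to a gene end (500 and 2500 bp) and to a gene body (50 kb or none), genes of all biotypes, overlap of at least 1 bp in place of the midpoint, other joining distances (5 and 25 kb), every chromosome the gene table holds, the outer 5 Mb of each chromosome left out, each peak moved by up to 500 kb in place of a free placement, no stretch excluded, random lists not matched or also matched on gene density, and lists without genes that belong to more than 1 list. Placements for these, for the distances to gene ends and for RNA genes numbered 200. The overlap of at least 1 bp was run for the placements and not for the gene lists.

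The code was tested on simulated data before use. With all 52765 peaks placed at random, the gene-end ratio was 0.980 and 0 of 18 lists were called over 19974 genes. Those simulated peaks formed 182 clusters of at least 5 peaks, where the data held 1970. How often lists are called by chance with peaks as clustered as in the data was therefore not simulated. With 5000 peaks planted at gene ends the ratio was 3.95, where 4.06 was planted. With 18 peaks planted at the genes of 1 list, that list was the 1 called. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.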

Results

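LDB1 is a nuclear adaptor protein that dimerises and joins LMO, GATA and basic helix-loop-helix factors into complexes that hold enhancers and promoters together. Its sites were mapped by CUT&Tag in untreated NB4 cells, a human acute promyelocytic leukaemia cell line that carries the PML::RARA fusion. There was 1 LDB1 library and 1 IgG library, with no replicate of either, so no value below has a replicate check. The question addressed was where LDB1 sits in these cells. The deposited LDB1 list held 53742 peaks, of which 52765 lay on chromosomes 1 to 22 and X. The peaks there had a median width of 550 bp (quartiles 408 and 816 bp, range 323 to 14368 bp) and covered 37.5 Mb. The depth behind the peaks was unknown, and positions and widths were the only values per peak. Whether the IgG library served as the caller's control is not given, so background in open chromatin may be among the peaks. Neither the placements nor the random lists were matched on open chromatin, so LDB1 binding and such background were not told apart. All coordinates are hg38, counted from 1.

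LDB1 peaks gathered at the ends of protein-coding genes. A peak midpoint lay within 1 kb of a gene end for 7882 of 52765 peaks, 14.9% (exact 95% interval 14.6 to 15.2%), against a mean of 3.07% (range 2.83 to 3.35%) in 1000 random placements, a ratio of 4.87. The rest of the gene bodies held 48.7% of the peaks (48.3 to 49.2%) against 44.3% in the placements, a ratio of 1.1. Sequence outside genes held 36.3% (35.9 to 36.7%) against 52.7%, a ratio of 0.690. None of these shares was reached in the 1000 placements. When each peak was instead moved by up to 500 kb, the gene-end ratio was 3.01 and the gene-body ratio turned to 0.959. With the ends of genes of all biotypes the gene-end ratio was 3.15.

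The excess was steepest next to the gene end. The 3058 peaks within 250 bp of a gene end were 7.11 times as many as in the mean of 200 placements. The ratio was 5.25 from 250 to 500 bp, 2.25 from 1 to 2 kb and 1.22 from 10 to 20 kb, and it fell below 1 beyond 20 kb. The median distance to a gene end was 12.6 kb. Wider peaks lay at gene ends more often. The share at gene ends was 10.8% (10.2 to 11.4%) in the narrowest of 5 equal groups of peaks (323 to 388 bp) and 20.8% (20.1 to 21.6%) in the widest group (913 to 14368 bp), while the share outside genes went from 39.4 to 30.1%. Of 5952 protein-coding genes longer than 20 kb with no other gene end within 5 kb of theirs, 2192 (36.8%) had a peak at 1 of their ends and 152 (2.55%) at both, where 261 at both would follow if the ends were independent. Strand was not used here, so which end holds the promoter is not given. Among all 19974 protein-coding genes, 7509 (37.6%) had a peak at an end and 13996 (70.1%) had a peak in the gene body or within 10 kb.

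**Figure D1:**
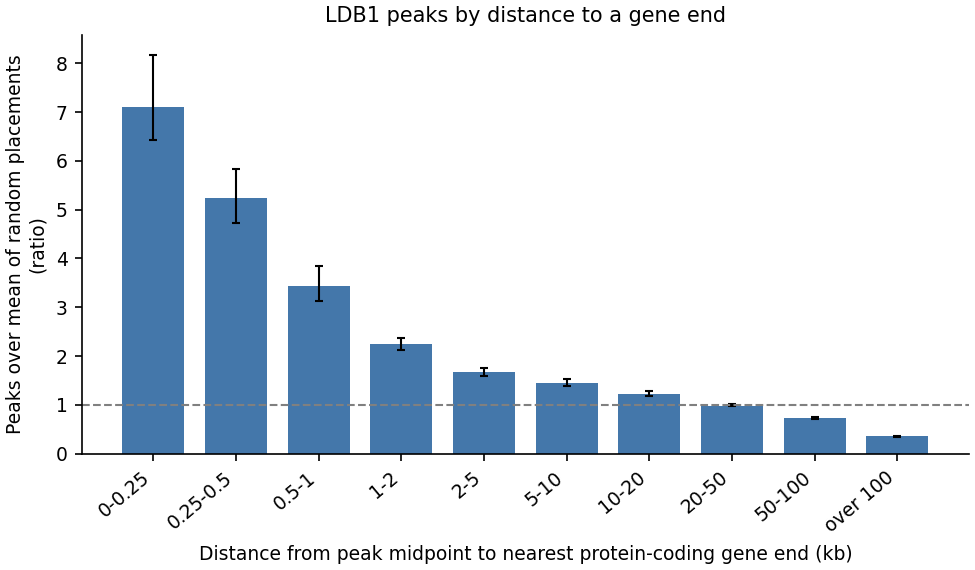
LDB1 peaks by distance from the peak midpoint to the nearest end of a protein-coding gene (kb, x axis), as the number of peaks over the mean of 200 random placements (y axis); error bars give the range over the placements and the dashed line marks 1. The ratio was 7.11 within 250 bp, 1.22 from 10 to 20 kb and 0.355 beyond 100 kb.

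Genes for myeloid transcription factors carried LDB1 peaks more often than other genes of like length. Of the 20 genes on that list, 14 (70.0%) had a peak at a gene end, where the random lists averaged 37.0% and 24 of 10000 reached as many. A peak lay in or within 10 kb of 19 of the 20, against a mean of 64.8% (22 of 10000), while the median of 3 peaks per gene was not called (104 of 10000), though it was with the widest 50% of peaks (22) and with the gene body only (2). The exception was CBFB, which encodes the partner of RUNX proteins. For genes of the lists, here and below, peak counts and widest peaks take in the gene body and 10 kb to either side. The same peak can therefore count for neighbouring genes and can lie outside the gene named. SPI1, the gene of the myeloid master regulator PU.1, had 2 peaks, the wider of them 3769 bp (chromosome 11, 47375286 to 47379054). CEBPE, needed for late granulocyte maturation, had 9 peaks with the widest at 3005 bp, and CEBPA had 3 with the widest at 1720 bp. Both genes of the NB4 fusion had peaks by this measure, as did 70.1% of all protein-coding genes. RARA had 8 peaks and PML had 3, with the widest at 1057 and 1327 bp. The widest one counted for PML lies outside the gene, and PML had no peak at a gene end. JUNB had 7 peaks, CEBPB and RUNX3 each had 6, and IRF8 had 4. The gene-end call was lost with a distance of 2500 bp, where 118 random lists reached the share, with the widest 25% of peaks (162) and without genes shared with other lists (62). The call for peaks within 10 kb was lost with the widest 25% of peaks (79), at 50 kb (270), without length matching (87) and without shared genes (66).

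Genes of granulocyte function lay inside the range of random lists. Of 25 such genes, 8 (32%) had a peak at a gene end and 16 (64.0%) had one within 10 kb, where random lists averaged 37.2 and 65.7%. LCN2, which encodes the iron-sequestering protein of secondary granules, had 4 peaks with the widest at 2315 bp. LTF, the lactoferrin gene, had 7 with the widest at 1686 bp, and CYBA, a subunit of the phagocyte oxidase, had 7. Among primary granule genes, AZU1 had 5 peaks, MPO and PRTN3 had 3 each, and ELANE had 1 of 332 bp. The ELANE peak lies inside PRTN3, and the widest peak of PRTN3 reaches across an end of AZU1, so these neighbours share peaks. NCF1 had 5 peaks, which are uncertain because the gene has near-identical copies. No peak lay within 10 kb of CTSG, CTSC, SRGN, RNASE2, RNASE3, CAMP, MMP8, CYBB or NCF4. Whether the granulocyte list differed from the myeloid factor list was not tested.

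Genes that answer to retinoic acid, the agent that drives NB4 cells to differentiate, also carried LDB1 peaks in these untreated cells. A peak lay in or within 10 kb of 19 of the 20 genes (95%), against a mean of 67.6% (36 of 10000 random lists), and the median was 4 peaks per gene against 1 (18 of 10000). At gene ends the count was 13 of 20, which 94 random lists reached, so it was not called; it was called at 2500 bp (28), with the widest 50% of peaks (18) and with the widest 25% (35). CYP26B1 and CYP26A1, which encode enzymes that degrade retinoic acid, had 8 and 3 peaks with the widest at 3340 and 1600 bp. TGM2, the tissue transglutaminase gene, had 11 peaks, with the widest at 1660 bp. CEBPE had 9 and RARA had 8, and both are also on the myeloid list, so the calls of these lists are not independent. Another gene is also on the monocyte list. The gene without a peak was TNFSF10, which encodes the death ligand TRAIL. The call for peaks within 10 kb was lost at 50 kb (1666 random lists), without length matching (65), with matching on gene density as well (78) and without genes on other lists (118), and that for the median was lost with the gene body only (122).

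**Figure D2:**
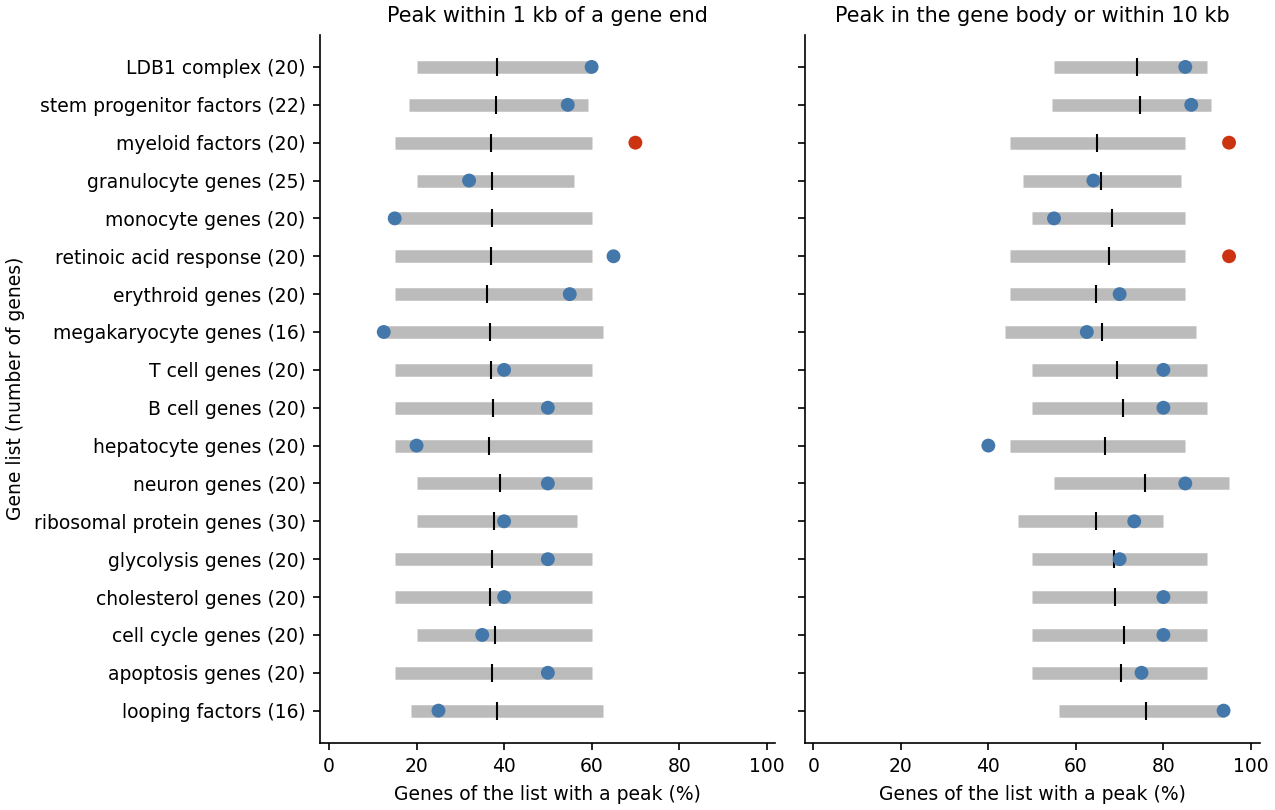
Share of the genes of each of the 18 lists (rows, with the number of genes) that had an LDB1 peak within 1 kb of a gene end (left) or in the gene body or within 10 kb (right), in percent. Points are the lists, red where at most 50 of 10000 random lists reached the share; grey bars hold the central 95% of the length-matched random lists and black ticks their mean. The myeloid factors stand at 70.0% and 95%, and the retinoic acid genes at 65.0% and 95%.

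The genes of the LDB1 complex itself were dense in LDB1 peaks. The list of 20 genes had a median of 5 peaks in or within 10 kb of the gene against 1.5 in random lists, reached by 4 of 10000. By share it was not called: 17 of 20 (85.0%) had a peak within 10 kb and 12 of 20 (60.0%) had one at a gene end, which 395 random lists reached. With the widest 25% of peaks the gene-end share was called (14 random lists). LYL1, the gene of a basic helix-loop-helix factor of early blood cells, had 10 peaks, the widest of 5476 bp over its end (chromosome 19, 13100233 to 13105708). CBFA2T3, which encodes the corepressor ETO2, had 16 peaks, the widest of 8234 bp (chromosome 16, 88971380 to 88979613). That peak reaches across an end of CBFA2T3, but its midpoint lies 1.71 kb away, so the gene is not among those counted at a gene end. TCF3, the gene of the E2A factors, had 17 peaks (widest 4580 bp), SSBP3, which encodes a single-stranded DNA binding partner of LDB1, had 20, and TAL1 had 10 (widest 2135 bp). GATA1, GATA2 and KLF1 had 5, 8 and 5 peaks, with the widest at 2352, 1822 and 1945 bp. LDB1 had 5 peaks in or within 10 kb of its own gene, and LMO2 had 5, none wider than 461 bp. No peak lay within 10 kb of LDB2, TCF12 or RLIM. The call for the median was lost with the widest 50% of peaks (149 random lists), the widest 25% (792), the gene body only (1572) and without genes on other lists (88). CBFA2T3 lies in the last 5 Mb of chromosome 16 and TCF3 in the first 5 Mb of chromosome 19. These ends held 3.92 and 2.75 times the peaks expected from the number of genes, so the counts of both genes may reflect their region. The call for the median held without the outer 5 Mb of chromosomes (5 random lists).

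Factors of blood stem and progenitor cells showed a like density, with a median of 5 peaks in 22 genes against 1.5 in random lists (1 of 10000). A peak lay within 10 kb of 19 of 22 genes (86.4%) and at an end of 12 (54.5%), neither of which was called. ZFPM1, which encodes the GATA cofactor FOG1, had 32 peaks, the widest of 12089 bp inside the gene (chromosome 16, 88488893 to 88500981). RUNX1 had 8 peaks, with the widest at 3118 bp, and MYB had 2, with the widest at 3295 bp. GFI1B, a repressor gene of erythroid and platelet lineages, had 7 (widest 2797 bp), and NFE2 had 7 (widest 2173 bp). IKZF1 had 9, HOXA10 had 8 and HOXA9 had 7, and the widest peak counted for HOXA9 and for HOXA10 is the same. KIT and CD34, which encode surface proteins of progenitors, had 2 and 4 peaks, all under 1 kb wide. ERG, ETV6 and FLT3 had none. ETV6 lies in a run of 37 neighbouring genes of chromosome 12 without a peak within 10 kb, so its absence is not particular to it. LMO2, TAL1 and GATA2 are also on the LDB1 complex list. The call was lost at 50 kb, where 122 random lists reached the median. ZFPM1 lies in the last 5 Mb of chromosome 16, which held 3.92 times the peaks expected from the number of genes. Its count may therefore reflect its region. The call held without the outer 5 Mb of chromosomes (1 random list).

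**Figure D3:**
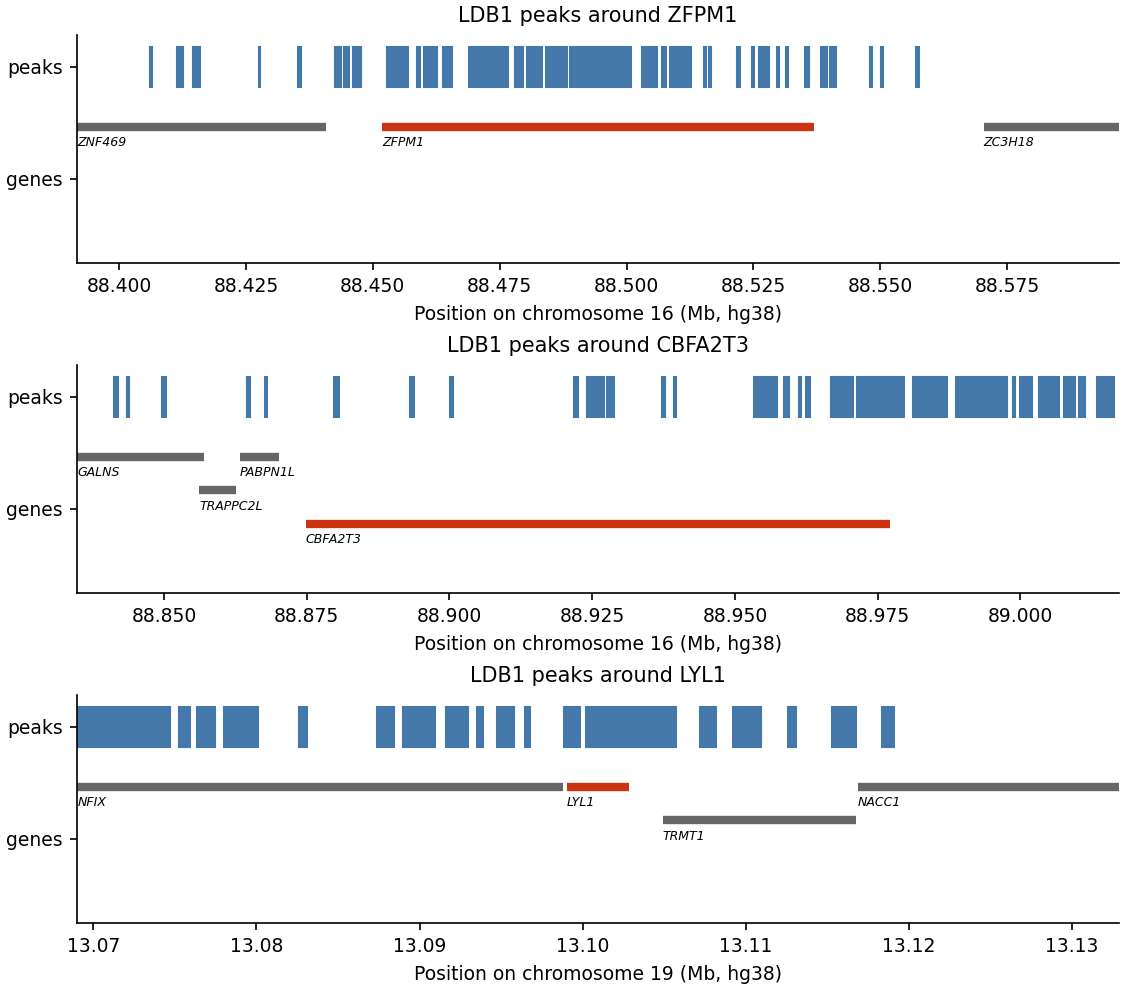
LDB1 peaks (blue boxes) and protein-coding genes (bars, the named gene in red) around ZFPM1 and CBFA2T3 on chromosome 16 and LYL1 on chromosome 19; the x axis is the hg38 position in Mb and the height of the boxes carries no value. The widest peak shown lies inside ZFPM1 (12089 bp), and the 8234 bp peak of CBFA2T3 and the 5476 bp peak of LYL1 lie across an end of their genes. ZFPM1 and CBFA2T3 lie in the last 5 Mb of chromosome 16, which held 3.92 times the peaks expected from the number of genes.

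Lists of sister blood lineages lay inside the random range by share. The erythroid list had peaks at an end of 11 of 20 genes (653 random lists) and a median of 3 peaks (149). Its gene-end share was called with the widest 25% of peaks (0 of 10000), and its median was 1 without the outer 5 Mb of chromosomes (8901). Its widest peaks lay in or within 10 kb of SLC4A1, the gene of the red cell anion exchanger band 3 (12 peaks, widest 4319 bp), GATA1, ANK1 (31 peaks, widest 1976 bp) and KLF1. HBB had no peak within 10 kb, nor had HBG1 and HBG2, which are near-identical copies and so uncertain. The megakaryocyte list had peaks at an end of 2 of 16 genes (370 random lists had as few) and within 10 kb of 10. GP1BB, GP9, TUBB1 and ITGA2B had its widest peaks (5839, 2321, 1628 and 1538 bp), and PF4, PPBP and GP1BA had none. The GP1BB peak reaches across an end of that gene, but its midpoint lies over 1 kb away, so GP1BB is not among the 2. The monocyte list had peaks at an end of 3 of 20 genes (304 had as few) and within 10 kb of 11. Its widest peaks lay in or within 10 kb of VCAN (2396 bp), S100A8 (1440 bp), CD68 (1366 bp) and S100A9 (1031 bp). Those of CD68 and S100A9 lay outside the gene. FCGR3A, which has a near-identical copy, CD163 and MRC1 had none. AIF1 and LILRB4, named after their values were seen, also had none, and they lie in runs of 64 and 27 neighbouring genes without a peak within 10 kb. Part of the LDB1 peaks lay on alternate copies of such regions, 70 on those of the chromosome 6 region and 34 on all alternate contigs of chromosome 19, so the absence at both genes is uncertain. The same holds for GP6 of the megakaryocyte list, which lies in the run on chromosome 19 and was also named after its value was seen, and for the counts of both lists that include such genes.

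T cell, B cell, hepatocyte and neuron genes gave no call either. T cell genes had peaks within 10 kb of 16 of 20 and B cell genes of 16 of 20. CD7, an early T cell and myeloid antigen gene, had 9 peaks with the widest at 4629 bp. CD247, TCF7 and GATA3 followed at 1620, 1393 and 1271 bp, and CD3G and TRAT1 had none. TRAT1 lies in a stretch of chromosome 3 with 12 genes and no peak, so its absence is not particular to it. Among B cell genes CD22, EBF1, BLK and TNFRSF13C had the widest peaks (2368, 2152, 1355 and 1347 bp), and MS4A1, BLNK and RAG2 had none. Hepatocyte genes were the list with the lowest share within 10 kb, 8 of 20 (40%), which 150 random lists matched or undercut. TF, the transferrin gene, had 8 peaks with the widest at 2683 bp, APOA1, APOB and CYP2E1 had their widest at 1270, 1090 and 854 bp, and ALB, TTR and FGA had none. Neuron genes had a peak within 10 kb of 17 of 20, with 30 peaks at RBFOX3 (widest 1869 bp). RBFOX3 lies in the last 5 Mb of chromosome 17, which held 3.49 times the peaks expected from the number of genes. NEFM, SYN1 and CNTNAP2 came next (1709, 1336 and 1227 bp), and SYT1 and GRIA1 had none.

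Genes of general cell functions lay inside the range of random lists. The counts with a peak within 10 kb were 22 of 30 ribosomal protein genes, 14 of 20 glycolysis genes, 16 of 20 cholesterol genes, 16 of 20 cell cycle genes, 15 of 20 apoptosis genes and 15 of 16 genes of chromatin looping factors such as RAD21 and STAG2. At gene ends the counts were 12 of 30, 10 of 20, 8 of 20, 7 of 20, 10 of 20 and 4 of 16. SLC2A1, the gene of the glucose transporter GLUT1, had 13 peaks with the widest at 3730 bp, and GAPDH had 3 with the widest at 2777 bp. MYC had 3 with the widest at 2232 bp, and CCND3, a cyclin D gene, had 17. BBC3 and BAX, which encode pro-apoptotic proteins, had peaks of up to 3034 and 2302 bp, RPL18 of up to 2609 bp, and SCAP of up to 2440 bp. CDK1, CDK2 and CDKN2A had none, and CDKN2A lies in a stretch of 9.29 Mb of chromosome 9 that holds no peak.

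Of the 10 widest LDB1 peaks with a midpoint over 1 kb from any gene end, ZFPM1 and CBFA2T3 were each nearest to more than 1. The widest of all, 14368 bp, had its midpoint inside COL18A1, a collagen gene, and reached across an end of it (chromosome 21, 45402357 to 45416724). It was followed by 13369 bp inside MAD1L1, a spindle checkpoint gene (chromosome 7, 1852063 to 1865431), and by the 12089 bp peak inside ZFPM1. A peak of 9181 bp lay inside RXRA, the gene of the partner receptor of RARA (chromosome 9, 134333947 to 134343127). A further 9153 bp lay inside INTS1 (chromosome 7), 8884 bp lay 15.9 kb outside CBFA2T3, and 8394 bp lay 19.8 kb from SEMA7A. The remaining peaks of the widest 10 lay at CBFA2T3 (8234 bp), LOC124905153 (7694 bp) and ZFPM1 (7590 bp). The peak at LOC124905153 and the 8234 bp peak at CBFA2T3 also reached across a gene end, so 3 of these 10 did. The peaks nearest to COL18A1, MAD1L1, ZFPM1, RXRA, INTS1 and CBFA2T3 lie in the outer 5 Mb of a chromosome. The start of chromosome 7 held 11.08 times the peaks expected from the number of genes. At the ends of chromosomes 16 and 21 the ratios were 3.92 and 3.5. The end of chromosome 9 held 333 peaks where 175 were expected. The widths of these peaks may therefore reflect their region, which was not tested. The peaks at SEMA7A and LOC124905153 lie elsewhere. At gene ends the widest were at GUK1, a guanylate kinase gene (8936 bp, chromosome 1, 228144200 to 228153135), TMC8 (7985 bp) and ACTB, the beta-actin gene (6556 bp), then LYL1, GRIFIN (5263 bp), TXNRD2 (5166 bp) and HMX3 (4906 bp). LOC124900189, HSF1, the heat shock factor gene, and NHLRC4 completed the 10 (4865, 4709 and 4683 bp). GRIFIN, LOC124900189, HSF1 and NHLRC4 also lie in the outer 5 Mb of a chromosome.

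LDB1 peaks stood in clusters. There were 1970 clusters of at least 5 peaks joined at 10 kb or less, against a mean of 191 (range 157 to 232) in 1000 placements, and they held 19302 peaks (36.6%). The cluster with the most peaks, 160, spanned 510 kb of chromosome 7 (1169811 to 1679618) with UNCX, MICALL2, INTS1, MAFK, TMEM184A, PSMG3 and ELFN1; MAFK encodes a small partner of NFE2. The next, with 144, lay over GSE1 on chromosome 16 (85202284 to 85663484). Chromosome 7 held the other leading clusters as well. They had 135 peaks around WIPI2, SLC29A4, TNRC18, FBXL18, ACTB, FSCN1 and RNF216 (5203677 to 5638050), 133 around LOC112268384, PDGFA, PRKAR1B and DNAAF5 (368277 to 811010) and 120 over MAD1L1 (1809717 to 2180122). These regions of chromosome 7 lie where peaks were densest along the chromosome. The ratio of clusters over placements, 10.3, was 1.56 when each peak was moved by up to 500 kb, 1.88 with a joining distance of 25 kb and 41.3 with 5 kb.

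Chromosomes 19, 22, 17, 7 and 16 were richest in peaks. The mean was 18.5 peaks per Mb, and chromosome 19 had 62.6, chromosome 22 had 44.0, chromosome 17 had 33.9, chromosome 7 had 27.8 and chromosome 16 had 27.5. The lowest were chromosome 13 with 7.93 and chromosome X with 8.63. Of the 23 chromosomes, 8 lay above the range of even placement, 12 below and 3 within it. Chromosome 7 had the most peaks per protein-coding gene, 4.63 against 2.64 over all chromosomes, and X the fewest, 1.54.

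**Figure D4:**
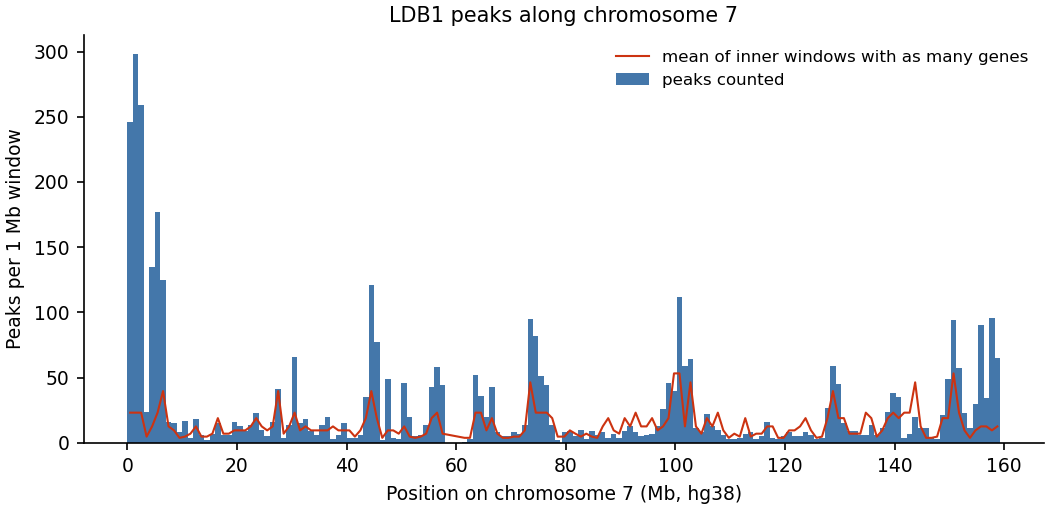
LDB1 peaks in windows of 1 Mb along chromosome 7 (bars; x axis, hg38 position in Mb; y axis, peaks per window), with the mean number of peaks in inner windows of all chromosomes with as many genes (red line). The first 5 Mb held 962 peaks where 86.8 followed from the number of genes.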

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

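Part of the list lay outside the chromosomes analysed in the report and stood above the limit that a count of 0 allows. On 147 alternate contigs, which are second versions of regions of the main chromosomes, there were 719 peaks, with a median width of 482 bp. On 49 unplaced or unlocalised contigs there were 244 peaks, with a median width of 559 bp, close to the 550 bp of the main set. The rest of the 977 peaks outside chromosomes 1 to 22 and X lay on chromosome Y. With Y the main set would hold 52779 peaks in place of 52765. The tests in the next paragraph were chosen after the result was seen.

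The longest run of neighbouring protein-coding genes with no peak within 10 kb was in the major histocompatibility region of chromosome 6 (30908207 to 32035418, GTF2H4 to C4B). It held 64 genes, and 1 peak lay between them, more than 10 kb from each. The genes that bound these runs were named after their values were seen. From the start of that run to the end of a further run of 23 genes (HLA-DOA to ZBTB9, ending at 33457544) there were 10 peaks in 2.55 Mb, and the next 1 Mb held 101. The 7 alternate copies of the region held 70 peaks, 2 to 20 on each, but these could not be placed over the same 64 genes, since the copies extend beyond the run and no map of their genes was used. Reads shared between chromosome 6 and its copies, if set aside on the main chromosome, may therefore account for the few peaks, AIF1 included. Loss of DNA of the run in these cells may do so too, though loss of all of it would leave none for the 1 peak listed there. The 70 peaks do not decide between shared reads and such loss. No biological explanation was tested.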

How the results depend on the processing

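Alternatives with the widest peaks, without the outer 5 Mb, with peaks moved by up to 500 kb, with no stretch excluded, with gene density matching and without shared genes, and those of the gene-body share and of the median number of peaks, were chosen after seeing the data. The gene-end ratio stayed above 1 and beyond the placements in all settings run (3.01 to 6.31), the ratio outside genes stayed below 1 (0.588 to 0.821), and chromosome 7 stayed above the genome mean (1.34 to 1.93). The gene-body ratio turned from 1.1 to 0.959 when each peak was moved by up to 500 kb, which compares a peak with its own surroundings; the cause was not tested. Clusters numbered 780 with the widest 50% of peaks and 310 with the widest 25%, against 1970, as fewer peaks entered, yet stood 37.8 and 190 times above the placements. At gene ends 1 list was called; with the widest 50% of peaks there were 2, with the widest 25% 3 and without genes in more than 1 list 0. Within 10 kb 2 lists were called; there was 1 with the widest 25% of peaks, 0 at 50 kb, 0 with random lists not matched, 1 with matching on length and gene density and 0 without genes in more than 1 list. The causes were not tested, though the last setting has fewer genes per list. Over all alternatives, the calls of single lists at gene ends held in 4 comparisons and were lost in 3, those within 10 kb held in 8 and were lost in 8, and those of the median held in 18 and were lost in 6. Lists with no call gained one in 5 comparisons at gene ends, 0 within 10 kb and 2 for the median. Not run for want of values or sequence were the thresholds on q, the filter on repeats, the motif searches and matching on promoter GC. Depth was unknown, so a gene without a peak cannot be told from one below detection.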

Other observations

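Tests of the gene families, RNA genes and peak widths below, and those of DNA loss, of the interferon family and of the step along chromosome 7, were chosen after the data were seen, as were the genes named in this part. Several tissue-restricted gene families had few LDB1 peaks. Of 392 olfactory receptor genes, 11 (2.81%) had a peak at a gene end where random lists averaged 36.4%, and 0 of 10000 had as few. Keratin-associated protein genes had 11 of 94 and beta-defensin genes 2 of 39, again with 0 of 10000 random lists as low. Within 10 kb the counts of these families were 58, 21 and 7. Keratin genes had 12 of 55 at an end, which was not called (80 of 10000 as low), and 23 of 55 within 10 kb, which was (2). Many of these genes have close copies, which makes their counts uncertain. Histone genes were at the other end, with 60 of 94 (63.8%) against 35.6%, and so were HOX genes, with 27 of 40 (67.5%) against 37.1%, both reached by 0 of 10000. Peaks were dense over the HOX clusters, with 24 in 107 kb at HOXA, 26 in 103 kb at HOXD, 15 in 117 kb at HOXC and 19 in 200 kb at HOXB. Within 10 kb, 52 of 53 protocadherin cluster genes and 46 of 52 FOX genes had a peak (random means 76.4 and 65.1%), while their counts at gene ends, 27 and 25, were not called (694 and 742 of 10000). ZNF genes had 316 of 517 within 10 kb (61.1% against 69.6%, 1 of 10000 as low) and 166 at an end, which was not called (105 as low). SH domain genes, grouped by symbol, were also called above, with 25 of 38 at an end (3 of 10000) and 36 of 38 within 10 kb (14). Interferon alpha genes, in the stretch of chromosome 9 without peaks, had 0 of 13 by both measures and were called below. Collagen, solute carrier, T-box and SOX genes were called by neither measure. These are all the families tried. Many of these families stand in tight clusters, where 1 peak can count for several neighbours, and the random lists draw scattered genes, so that they understate the chance spread.

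Genes for non-coding RNAs were each set beside random placements, and their classes were not compared with each other. Peaks overlapped 187 of 1911 microRNA genes (9.79%, exact 95% interval 8.49 to 11.2%), 5.68 times the mean of 200 placements. The ratio was 3.75 for snRNA genes (14 of 154) and 4.85 for rRNA genes (13 of 49), whose near-identical copies make both uncertain. It was 2.06 for tRNA genes (14 of 443), which 4 of 200 placements reached, and 0.586 for snoRNA genes (11 of 1196), with 9 of 200 placements as low. For long non-coding RNA genes it was 1.02 (26.6%), reached by 6 of 200 placements. Pseudogenes and transcribed pseudogenes, which can share sequence with their parent genes, had ratios of 1.70 and 1.36 (0 of 200). The widest peak of a gene rises with the number of its peaks, for which no control was run. The median gene of the LDB1 complex list had its widest peak at 1377 bp, that of the stem and progenitor list at 1447 bp and that of the retinoic acid list at 1314.5 bp, against 631, 628.5 and 557.5 bp in random lists, and 0 of 10000 reached any of them. The erythroid median was 1061 bp (15 of 10000) and that of the myeloid factors 887.5 bp (187 of 10000), while the granulocyte median was 448 bp (7402 of 10000 as high). Clusters of 94 and 54 peaks lay over ABL1 (with neighbours, chromosome 9, 130850794 to 131124696) and BCR (chromosome 22, 23141707 to 23290031). Both were picked after the clusters were seen, and other clusters of 81, 80 and 71 peaks lay on chromosomes 8, 22 and 16. No link between the ABL1 and BCR clusters was tested. A stretch of chromosome X with 13 genes, among them CSF2RA and IL3RA (274806 to 2264227), held no peak; it lies in the pseudoautosomal region, whose sequence has an identical copy in the genome, so this absence is uncertain.

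Peaks crowded toward chromosome ends, most at the start of chromosome 7. The outer 5 Mb of 42 chromosome ends held 21.4% of the peaks and 13.3% of the genes, 2.252 times the peaks expected from inner windows with as many genes (1.81 to 2.79 when ends were resampled; 2.06 without chromosome 7), so gene density alone is argued against; 34 of the 42 ends lay above 1. The start of chromosome 15 was counted among these ends, with 15 genes and 0 peaks where 46.6 were expected. The positions of those genes were not checked, so that end may not be real. The first 5 Mb of chromosome 7 held 962 peaks where 86.8 followed from its 47 genes, a ratio of 11.08. Among inner windows of 1 Mb, 95% lay below 2.68 and the highest reached 19.3, and of 454 inner blocks of 5 Mb the highest reached 3.43, so the number of genes alone is argued against here too. The ratio at the start of chromosome 7 was 7.952 times that of its inner windows. Extra copies of the whole chromosome need not raise peak numbers by the same factor throughout, because a peak is listed only above an unknown threshold. This step therefore does not decide whether there were extra copies. The ratio of the inner windows, 1.39, met neither bound set beforehand against extra copies. It reached the size named for them, though 2 other chromosomes were as high, so extra copies stay open. A local gain of this part of chromosome 7 and the GC-rich, repeat-rich sequence near chromosome ends stay open as candidate explanations, since neither copy number nor sequence was used here, and no biological explanation was tested.

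A stretch of 9.29 Mb on the short arm of chromosome 9 (19896035 to 29189325) held 0 peaks and 38 protein-coding genes, from MLLT3 to LOC124902135 with MTAP, CDKN2A and CDKN2B among them, while the peak-free stretch over 1 Mb with the next most genes outside the olfactory receptor family held 35. Of its genes 17 are interferon genes, and 21 are not, which is fewer than in 1 of the 195 other such stretches and more than in the rest, the next lower holding 13. A comparison of these 21 genes with random genes would say nothing, because the stretch was chosen for holding no peak, and whether the interferon family plays a part stays open. Thin coverage of the area stays open: 62.79% of the 43 flanking genes had a peak against 73.2% at random (872 of 10000 as few), which by the bound set beforehand would argue against it, but the 10 flanking windows held 52 peaks where 134 were expected, so that bound on genes was too lenient. Loss of this DNA in NB4 cells may explain it too, yet a list with 0 peaks in the stretch is what any cause would give. No biological explanation was tested.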
